A study of Mus musculus with 6 samples.

How the data were processed

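RNA from flow-sorted mouse bone marrow cells was measured on 6 single-colour 3' expression arrays. Per the labels, the cells were stem and progenitor cells negative for Flt3 and lineage markers and positive for Sca1 and cKit, from mice on a C57BL/6 background whose Raptor alleles both carried loxP sites around exon 6. The 3 arrays of the Raptor mutant group came from mice with the Mx-Cre transgene, in which the recombinase Cre is driven by an interferon-responsive promoter. The 3 arrays of the wild type group came from mice without it. Both groups received polyinosinic-polycytidylic acid (pIpC), an inducer of interferon, at 15 µg per g body weight in 3 injections over 5 days, with the sort 5 weeks later. Per the labels' protocols, RNA was extracted with a PicoPure kit, amplified with the Ovation Pico WTA system and labelled with biotin.

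The authors deposited 1 intensity per probe set and array, made with RMA per the submitters' processing notes (background correction, normalization across arrays and summary of probes into probe sets). The version and settings of RMA are not given in the sources used here. The deposited intensity values are on a linear scale, from 7.6 to 33795, with array medians of 115 to 123, so log2 was taken before every test. The number of arrays limits the precision, and array data carry no read depth. Arrays did not repeat one another: at most 99 of 45101 probe sets were identical between any pair. The labels number the arrays of each group 1 to 3, and nothing in them says whether each array stands for a separate mouse or a pool, so p-values measure the spread between these arrays, which may be partly technical.

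Of 45101 probe sets, 64 were array controls, 9160 named no gene in the annotation table used here, 932 named several genes and 34945 named a single gene. Entrez identifiers of 34741 of these matched the GRCm38.p6 gene table, which was used for names alone, and 0 symbols needed an update. Coordinates are not reported, since the build behind the probe sets is not given in the sources used here. Control probe sets and those naming no gene or several were left out. For the 9010 genes with more than 1 probe set, the one with the highest mean over all 6 arrays was used, which gave 18193 genes. No filter on dim genes was applied in the main test.

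Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust fitting) on log2 values, mutant minus wild type, with 3 arrays per group and no covariate. P-values are two-sided and were adjusted with the Benjamini-Hochberg method over all genes. A gene is called changed at an adjusted p under 0.05. Errors of log2 fold changes are standard errors (SE) of limma, and errors of group means are standard deviations (SD). A total of 30 gene lists was fixed before the data were examined, as were the tests, the rule for named genes and most alternatives. Lists of at least 5 measured genes were tested with camera of limma, which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and again with the correlation estimated from the arrays, adjusted over the 30 lists. For each list the members that passed are counted with p adjusted over the list alone and over all genes. The lists held 925 entries, of which 823 were measured, with older names used only where no current gene bears them. The rule for named genes took up to 12 genes per direction with the largest log2 change among those called whose groups do not overlap, without clone or predicted names, together with Rptor, Mtor, Rictor, Mlst8 and up to 4 members of each list with the smallest p in its direction. Other members are named where they passed within their list or were chosen after their values were seen, as the text says.

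The procedure was tested on simulated data for the mutant against wild type comparison over 18193 genes, with 200 genes changed. It called 22 of 75 genes changed by 2-fold (29.3%), 66 of 75 changed by 4-fold (88.0%) and 44 of 50 changed by 8-fold (88.0%), and 5 unchanged genes. In a simulated run of the 30 lists with 1 list shifted by 0.5, that list had a camera adjusted p of 1.4e-33 (0.0039 with an estimated correlation) and 0 other lists were called. Simulated genes varied independently, whereas estimated correlations within the real lists reached 0.236 (immediate early genes). The run therefore cannot show how often correlated genes give false list calls at the preset correlation.

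Alternatives were the replicate number as a block, median centring, quantile and cyclic loess normalization applied again, the mean of a gene's probe sets, every probe set as its own row, leaving out the lower 25% or 50% of genes by mean, eBayes with trend and robust fitting, array weights, adjusted p under 0.10, a fold of at least 2, camera with an estimated correlation or on ranks, and leaving out each array in turn. Alternatives chosen after the data were examined were Y-linked signal as a covariate (mean log2 of Eif2s3y and Kdm5d above 8), the same with an estimated correlation in camera, leaving out the arrays with that signal, and the stem cell list without Egr1 and Nr4a1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.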

Results

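Gene expression was measured in sorted bone marrow stem and progenitor cells of mice with an induced deletion in Raptor, the gene Rptor, and of control mice without the recombinase. Raptor is the defining subunit of the kinase complex mTORC1, which promotes growth in response to nutrients and growth factors. There were 3 wild type and 3 Raptor mutant arrays. The study asked which genes change when Raptor is lost from these cells, and the design implies a single comparison, mutant against wild type. Array medians lay between 6.85 and 6.94 on the log2 scale. Over all probe sets the 3 mutant arrays correlated with one another at r of 0.985 to 0.988. Wild type array 1 correlated with the mutant arrays at 0.977 to 0.984, and with wild type arrays 2 and 3 at 0.962 and 0.967. These are correlations across probe sets, which are not independent replicates. The median SD of a gene was 0.286 among wild type and 0.158 among mutant arrays.

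Sex-linked genes separated the arrays differently from the genotype. Xist, the RNA that coats the inactive X chromosome, had a log2 signal of 13.5 on wild type array 1 and of 13.4 on each of the 3 mutant arrays, against 8.05 and 5.69 on wild type arrays 2 and 3. The Y-linked gene Kdm5d stood at 10.6 and 9.53 on wild type arrays 2 and 3 and between 3.60 and 3.88 on the other 4 arrays. Y-linked Eif2s3y stood at 10.8 and 10.5 on those 2 arrays and between 3.95 and 4.53 elsewhere. The labels give no sex. All 3 mutant arrays and 1 wild type array therefore lacked Y-linked signal, so a comparison among arrays without it sets the mutants against wild type array 1 alone. The same holds for the genotype term of the fit with Y-linked signal as a covariate. No p-value from that fit measures a spread between wild type arrays without the signal.

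**Figure D1:**
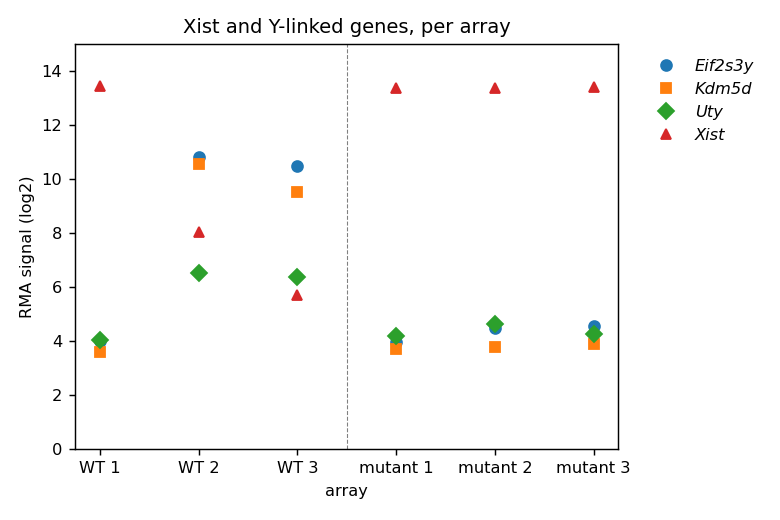
RMA signal (log2, vertical axis) of Xist and 3 Y-linked genes on each of the 6 arrays (horizontal axis), 1 point per gene and array, with a dashed line between wild type (WT) and Raptor mutant arrays. Y-linked Kdm5d lies at 10.6 and 9.53 on wild type arrays 2 and 3 and below 4 on the other arrays.

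The targeted gene was not called changed at any of the 3 probe sets that name it. The brightest Rptor probe set had a mean log2 signal of 8.11 ± 0.49 (SD, n = 3) in wild type and 8.33 ± 0.35 (SD, n = 3) in mutant arrays. Its log2 fold change was 0.22 ± 0.29 (SE), with a limma adjusted p of 0.77. The other Rptor probe sets had log2 fold changes of -0.32 and 0.99, with limma adjusted p of 0.69 and 0.56. Where these probes lie relative to exon 6 was not analysed here, so they check neither the deletion nor the labels. Of the partners of Raptor, Mtor, the kinase itself, had a log2 fold change of 0.32 ± 0.18 (adjusted p = 0.60, limma), and Mlst8 one of -0.29 ± 0.20 (adjusted p = 0.64, limma). Rictor, which defines the other mTOR complex, had one of 0.17 ± 0.28 (adjusted p = 0.82, limma).

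Of 18193 genes, 10 were higher and 10 lower in mutant than in wild type arrays. The largest increase was that of Gzmb, a serine protease of cytotoxic granules, whose log2 signal went from 5.51 ± 0.63 to 9.72 ± 0.55 (SD, n = 3 each), or 18.5-fold. No detection calls were used here, so folds of genes near background are not exact. The wild type means of Gzmb and Tmem215 (5.51 and 5.16) lay near the lower quartile of the arrays (5.15 to 5.37), and the mutant mean of Lipo3 (3.72) lay within the range of Kdm5d on arrays without Y-linked signal. The metallothioneins Mt1 and Mt2, small metal-binding proteins, rose 11.7-fold and 8.54-fold. Hpgds, the haematopoietic prostaglandin D synthase, rose 7.57-fold, and the transcription factor gene Bhlhe40 rose 5.81-fold. The largest decrease was that of Camp, the cathelicidin of neutrophil granules, which fell by 3.81 ± 0.42 (SE) on the log2 scale. On that scale the receptor gene Tek fell by 1.48, the lectin receptor gene Clec1a fell by 2.10 and the multimerin gene Mmrn1 fell by 2.30.

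The remaining increases were those of Tmem215, Anpep (aminopeptidase N), Rab34 (a small GTPase), Evc2 and Nek6 (a mitotic kinase), with log2 fold changes of 3.50 ± 0.22, 2.39 ± 0.22, 2.34 ± 0.26, 1.82 ± 0.21 and 1.51 ± 0.18 (SE). A dimmer of the 3 Tmem215 probe sets had a log2 fold change of -0.34. Among the decreases, Chil3, a chitinase-like protein of myeloid cells, fell by 2.68 ± 0.33, Lipo3 fell by 2.41 ± 0.18 and the transcription factor gene Sox6 fell by 2.34 ± 0.26 (SE, log2). Car3 (carbonic anhydrase 3) fell by 2.08 ± 0.25, the chemokine gene Ccl9 fell by 1.79 ± 0.22 and the interferon-induced Rsad2 fell by 1.43 ± 0.16. In all 20 genes the 3 mutant values lay on one side of the 3 wild type values.

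**Figure D2:**
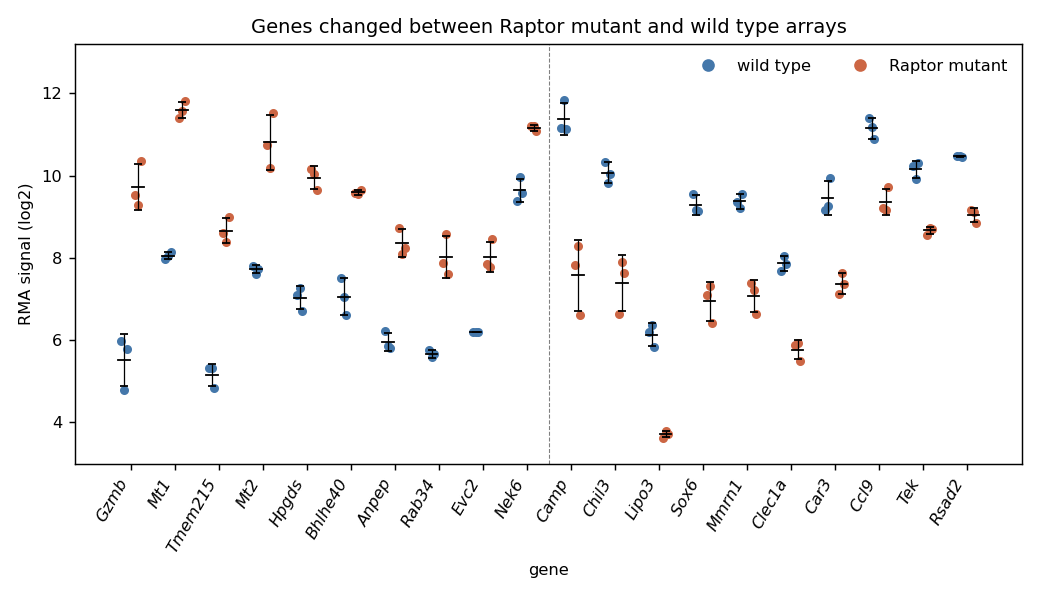
RMA signal (log2, vertical axis) of the 20 changed genes (horizontal axis), 1 point per array, wild type in blue and Raptor mutant in orange; horizontal lines are means and bars are SD over 3 arrays. Increases stand left of the dashed line, from Gzmb (5.51 to 9.72), and decreases right of it, from Camp (11.4 to 7.57).

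Adjusted p-values of the 20 genes in limma ran from 7.0e-04 for Mt1 to 0.043 for Nek6, Chil3 and Ccl9, and 1828 genes had an unadjusted p under 0.05. Groups did not overlap in 2921 genes (16.1%), where chance gives 10%. The count fell to 6 after quantile normalization was applied again, 8 with array weights and 12 with every probe set as its own row, and rose to 40 with trend and robust fitting. It was 31 without wild type array 1 (8 of the 20 genes among them), 5 without wild type array 3, and 10 and 9 without mutant arrays 1 and 3. With Y-linked signal as a covariate, which sets the mutants against wild type array 1 alone, all 20 genes kept their direction. Since the groups of these 20 genes do not overlap, that fit could not have changed it. In that fit the log2 fold changes were 3.62 for Mt1, 3.75 for Gzmb, -3.59 for Camp and -1.56 for Tek, but 2 genes in all were called. With the 2 arrays that carry that signal left out limma called 0 genes, with 1729 at an unadjusted p under 0.05.

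Of the 30 gene lists, 10 were shifted up and 5 down in mutant arrays by camera. With an estimated correlation 1 of these calls held, that of ribosome biogenesis. With Y-linked signal as a covariate and an estimated correlation 0 lists were called, and the smallest adjusted p was 0.097, for the stem cell list. Members called over all genes were 2 of the stem cell list (Mmrn1, Tek) and 1 each of the granulocyte (Camp), T and NK cell (Gzmb) and interferon (Rsad2) lists, and 0 of every other list.

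Genes of haematopoietic stem cells were lower in mutant arrays. Adjusted over the list alone, 13 of 33 measured members fell, 1 rose and 19 did not pass. Mmrn1 and Tek fell most clearly, followed by Mecom, a transcription factor gene of long-term stem cells, which fell by 0.996 ± 0.164 (SE, log2), and the receptor gene Robo4, which fell by 2.08 ± 0.37. The others that fell were Egr1, Hlf, Hoxa5, Hoxa9, Mllt3, Nr4a1, Pdzk1ip1, Procr and Vwf, and Ifitm1 rose, by 0.54 ± 0.15. The list's median log2 fold change was -0.58, with a camera adjusted p of 2.1e-06. The adjusted p was 0.144 with an estimated correlation. Its median was -0.74 with Y-linked signal as a covariate, a fit that sets the mutants against wild type array 1 alone.

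Genes of granulocytes and monocytes were also lower, with 10 of 25 members falling, 1 rising and 14 not passing when adjusted over the list alone. S100a8 fell by 3.13 ± 0.43 (SE, log2) and S100a9, the other subunit of calprotectin, fell by 2.87 ± 0.43, and Lcn2, lipocalin 2 of neutrophil granules, fell by 1.75 ± 0.30. Cebpa, a transcription factor gene of myeloid progenitors, rose by 0.86 ± 0.18. The early granule genes Mpo and Prtn3, chosen after their values were seen, had log2 fold changes of 0.16 ± 0.16 and 0.19 ± 0.19 and did not pass, and Elane of the same set had one of -0.59. The list's median was -0.59 (camera adjusted p = 0.0018, and adjusted p = 0.144 with an estimated correlation). Without wild type array 1 the camera adjusted p was 0.151, and on ranks it was 0.065. Against wild type array 1 alone, in the fit with Y-linked signal as a covariate, the median was -0.54. With the lower 50% of genes left out, the median was -0.12 over the 19 members that remain (camera adjusted p = 0.0012).

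Mast cell and basophil genes were higher in mutant arrays, and so were genes of macrophages and dendritic cells. Of 17 mast cell and basophil genes, 5 rose, 0 fell and 12 did not pass, adjusted over the list alone. Fcer1a and Ms4a2, the alpha and beta chains of the high-affinity IgE receptor, rose by 3.45 ± 0.55 and 2.77 ± 0.38 (SE, log2). Fcer1a stood at 7.49, 5.34 and 5.41 on wild type arrays 1, 2 and 3, and at 9.30 to 9.92 on mutant arrays. Prg2, a granule protein of eosinophils, rose by 2.30 ± 0.42, the chymase gene Cma1 by 2.15 ± 0.38, and the basophil protease gene Mcpt8 by 1.84 ± 0.34. This list had a median of 0.40 (camera adjusted p = 2.5e-06, and adjusted p = 0.121 with an estimated correlation). Of 26 macrophage and dendritic cell genes, 4 rose, 0 fell and 22 did not pass in the same way. They were C1qb, a complement component, by 2.57 ± 0.41, the class II genes H2-Aa and Cd74 by 2.13 ± 0.34 and 1.90 ± 0.41, and the lysosomal glycoprotein gene Cd68 2.83-fold. That list's median was 0.38 (camera adjusted p = 3.9e-05, and adjusted p = 0.121 with an estimated correlation). With Y-linked signal as a covariate, and so against wild type array 1 alone, the medians were 0.51 for the mast cell list and 0.48 for the macrophage list. With the lower 50% of genes left out, the medians were 0.77 over 7 mast cell genes and 1.17 over 8 macrophage genes, and with the lower 25% left out the mast cell median was 0.67 over 14.

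**Figure D3:**
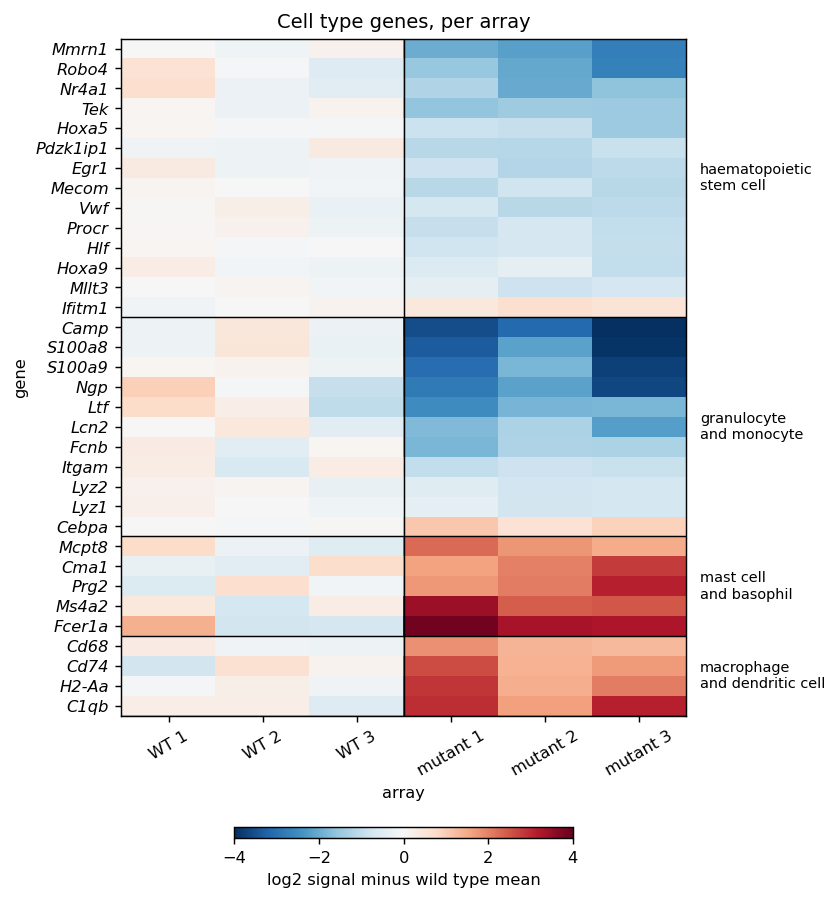
Log2 signal minus the wild type mean (colour, blue lower and red higher) of the members that passed within the stem cell, granulocyte, mast cell and macrophage lists (rows), on each of the 6 arrays (columns; WT, wild type). Camp (log2 fold change -3.81) and Fcer1a (3.45) mark the ends of the range, and the colour scale ends at 4 on either side.

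Megakaryocyte and platelet genes had a median of -0.40 over 22 members, of which 2 fell, 0 rose and 20 did not pass when adjusted over the list alone. These were Pf4, platelet factor 4, which fell by 1.73 ± 0.32 (SE, log2), and Vwf, which fell by 0.96 ± 0.20 and was also counted in the stem cell list. The camera adjusted p was 0.049, and the adjusted p was 0.320 with an estimated correlation. The camera adjusted p was 0.412 without wild type array 1 and 0.231 without mutant array 2. With Y-linked signal as a covariate, and so against wild type array 1 alone, the median was -0.28.

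The ribosome biogenesis list was shifted up in mutant arrays, with a positive log2 fold change in 35 of 39 members and a median of 0.26. The camera adjusted p was 8.9e-10, and the adjusted p was 0.043 with an estimated correlation. Adjusted over the list alone, 3 members rose, 0 fell and 36 did not pass. Nolc1, a nucleolar phosphoprotein, rose by 0.80 ± 0.17 (SE, log2), the RNA polymerase I subunit gene Polr1b by 0.79 ± 0.15 and Utp4 by 0.73 ± 0.17. Lysosomal genes were higher as well, with a median of 0.36 over 36 members, of which 5 rose, 0 fell and 31 did not pass within the list. Gpnmb rose by 3.32 ± 0.67, the cathepsin genes Ctss, Ctsb and Ctsd by 1.61 ± 0.37, 0.83 ± 0.17 and 0.66 ± 0.16, and the acid glucosidase gene Gaa by 0.97 ± 0.21. For this list the camera adjusted p was 7.8e-08, and the adjusted p was 0.121 with an estimated correlation. With Y-linked signal as a covariate, and so against wild type array 1 alone, the medians were 0.33 for ribosome biogenesis and 0.22 for the lysosome. The lysosomal median was 0.24 with the mean of a gene's probe sets.

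Cholesterol synthesis genes were lower, with 19 of 20 members below 0 and a median of -0.35. Adjusted over the list alone, 3 fell, 0 rose and 17 did not pass. Insig1, a sterol-regulated brake on the pathway, fell by 1.08 ± 0.21 (SE, log2), and the enzyme gene Msmo1 fell by 1.01 ± 0.21 and Idi1 fell by 0.81 ± 0.18. Immediate early genes, which respond within minutes to stimulation, had a median of -0.40, with 7 of 22 members falling, 0 rising and 15 not passing. The orphan receptor gene Nr4a1 fell by 1.61 ± 0.33, Btg2 fell by 1.10 ± 0.20, Egr1 fell by 1.02 ± 0.21 and Nr4a2 fell by 0.94 ± 0.26. Both lists had a camera adjusted p of 6.9e-05, and the adjusted p was 0.121 for cholesterol synthesis and 0.261 for immediate early genes with an estimated correlation. With Y-linked signal as a covariate, and so against wild type array 1 alone, the medians were -0.24 for cholesterol synthesis and -0.54 for immediate early genes.

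A further 6 lists were shifted up by small amounts and were not called with Y-linked signal as a covariate. Of 31 mTOR pathway genes, with a median of 0.17, Rragd, a lysosomal GTPase that recruits mTORC1, rose by 0.98 ± 0.23 (SE, log2), Sesn1 fell by 0.97 ± 0.21 and 29 did not pass within the list. Of 22 genes of the pentose phosphate pathway and nucleotide synthesis (median 0.21), the purine synthesis gene Atic rose by 0.77 ± 0.17 and 21 did not pass. No member passed among 22 glycolysis genes (median 0.15), 19 aminoacyl-tRNA synthetases (median 0.15), 24 heat shock and unfolded protein response genes (median 0.17) or 37 G2/M genes (median 0.12). Pfkp of glycolysis, Yars, Creld2 and Hmmr had the smallest p of these 4 lists, with log2 fold changes of 0.54, 0.62, 0.48 and 0.54. The camera adjusted p was 0.0063 for the mTOR list and for glycolysis, 0.0069 for nucleotide synthesis and the synthetases, 6.8e-04 for heat shock and 0.016 for G2/M. With an estimated correlation the adjusted p was 0.121 for mTOR, glycolysis and the synthetases, 0.144 for nucleotide synthesis, 0.261 for heat shock and 0.213 for G2/M. With Y-linked signal as a covariate it was 0.243 for mTOR, 0.221 for nucleotide synthesis, 0.231 for glycolysis, 0.153 for the synthetases, 0.523 for heat shock and 0.156 for G2/M. Without wild type array 3 it was 0.079 for mTOR and for the synthetases, 0.064 for nucleotide synthesis and 0.110 for G2/M, and without mutant arrays 1 and 2 it was 0.054 and 0.072 for G2/M. Without the lower 25% of genes the camera adjusted p was 0.053 for mTOR, glycolysis, nucleotide synthesis and the synthetases, and 0.104 for G2/M. Without the lower 50% it was 0.206 for mTOR and the synthetases, 0.207 for nucleotide synthesis, 0.485 for G2/M and 0.092 for heat shock. Glycolysis kept its call without the lower 50% and heat shock without the lower 25%. The median log2 fold change of all genes was 0.06 without the lower 50% and -0.07 in the main fit. Medians moved as well. Without wild type array 3 they were 0.05 for the synthetases, 0.13 for nucleotide synthesis and 0.06 for G2/M. Leaving out wild type array 1 gave 0.26 for mTOR and 0.06 for G2/M. The mTOR median was 0.11 after quantile normalization again and 0.10 with the mean of a gene's probe sets. The synthetase median was 0.09 after quantile normalization again and 0.08 without mutant array 2. In the fit with the Y covariate the medians were 0.13 for nucleotide synthesis and 0.07 for heat shock.

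**Figure D4:**
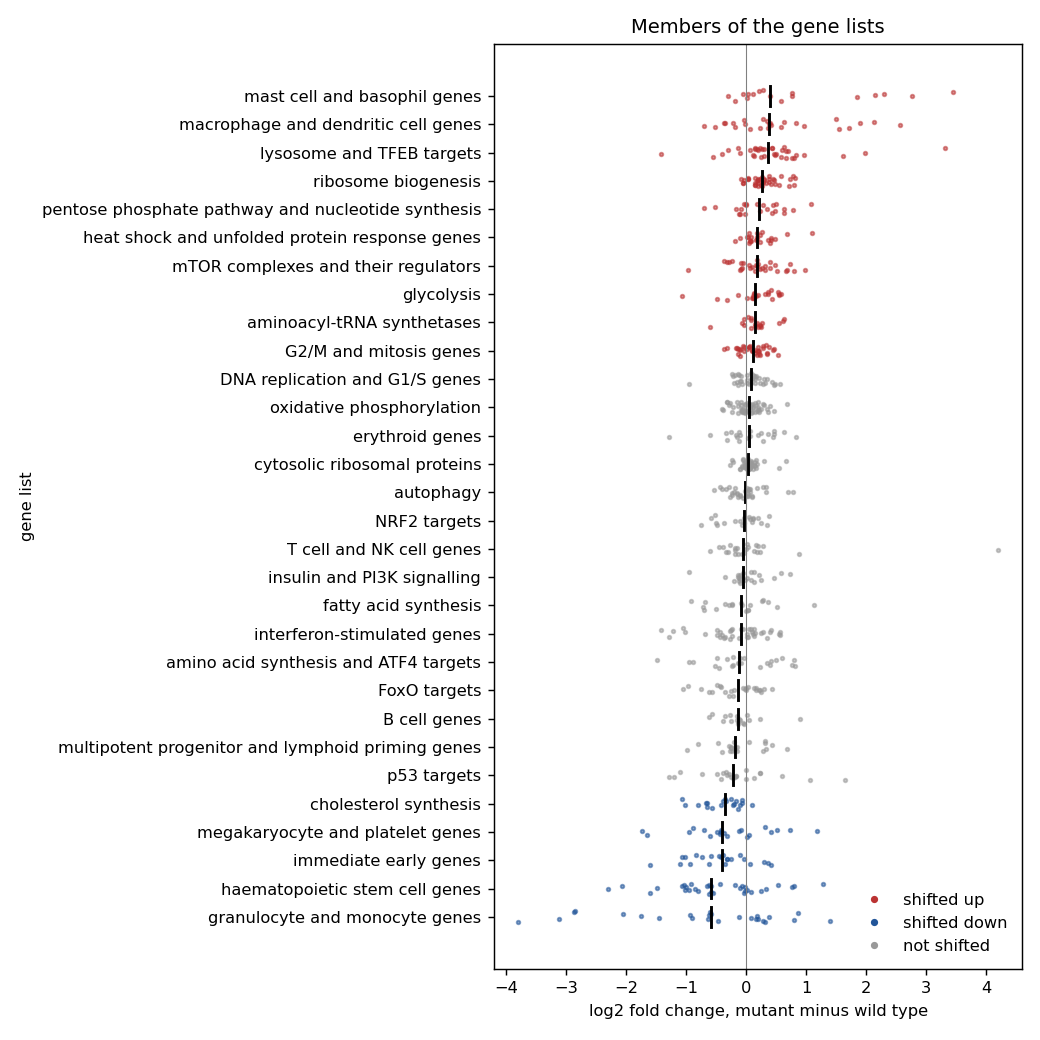
Log2 fold change, mutant minus wild type (horizontal axis), of each measured member (points) of the 30 gene lists (vertical axis), with the median of each list as a black bar. Colours mark the 10 lists shifted up, the 5 shifted down and those not shifted by camera at the preset correlation; medians run from -0.59 for granulocyte and monocyte genes to 0.40 for mast cell and basophil genes.

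The other 15 lists were not shifted. Cytosolic ribosomal protein genes (44 measured) had a median of 0.04 and a camera adjusted p of 0.101, and oxidative phosphorylation genes (54) a median of 0.04 and an adjusted p of 0.149. Among targets of the stress factor ATF4 (median -0.11, adjusted p = 0.933 by camera), Phgdh of serine synthesis and the transporter gene Slc7a5 rose by 0.80 ± 0.18 and 0.77 ± 0.20 (SE, log2), and Ddit4, an inhibitor of mTORC1, fell by 1.49 ± 0.29, all adjusted over the list alone. Among p53 targets (median -0.22, adjusted p = 0.143 by camera), Perp and Pmaip1 rose, and Btg2, Plk2 and Trp53inp1 fell, by the same criterion. Sesn1 and Sesn3 fell among FoxO targets (median -0.13, adjusted p = 0.149), Ifit1 and Rsad2 among interferon-stimulated genes (median -0.09, adjusted p = 0.185), and Gzmb and Cd28 rose among T and NK cell genes (median -0.05, adjusted p = 0.655). No member passed within the lists of insulin and PI3K signalling (median -0.06, adjusted p = 0.599), fatty acid synthesis (-0.08, 0.567), autophagy (-0.03, 0.940), G1/S (0.08, 0.060), lymphoid priming (-0.19, 0.587), erythroid (0.04, 0.930), B cell (-0.14, 0.185) or NRF2 genes (-0.04, 0.799). The direction of the test was upward while the median was below 0 for the insulin, ATF4 and T and NK cell lists. With Y-linked signal as a covariate, and so against wild type array 1 alone, the median was -0.37 for interferon-stimulated genes and -0.16 for FoxO targets. In the same fit it was 0.17 for oxidative phosphorylation, -0.18 for fatty acid synthesis, 0.09 for ribosomal proteins and -0.14 for autophagy.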

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

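The alternatives with Y-linked signal, alone or with an estimated correlation, and the stem cell list without Egr1 and Nr4a1, were chosen after the data were seen. Against 20 changed genes, the count was 6 with quantile normalization again, 40 with trend and robust fitting, 8 with array weights, 49 at an adjusted p under 0.10, 12 with every probe set as its own row, 2 with Y-linked signal as a covariate and 0 with arrays with Y-linked signal left out (1729 at an unadjusted p under 0.05 in limma). Leaving out single arrays gave 5 to 31 genes and 12 to 17 lists. The 2 extremes for genes were without wild type array 3 and without wild type array 1. The remaining settings, apart from the replicate block below, gave 15 to 29 genes. The 20 genes kept their direction in all 353 gene and setting pairs and their call in 200. Their groups do not overlap, so settings that drop, weight, block or adjust arrays could not have changed a direction. The causes were not tested, except that fewer arrays or degrees of freedom remain when arrays are left out or a covariate is added.

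Same-numbered arrays of the 2 groups did not deviate together (correlations of deviations 0.184, -0.026 and 0.063), so the numbers were not taken to pair them. With the replicate block, 10 genes were called, of which 7 were among the 20, and 14 of the 15 lists; the list that was not was that of megakaryocyte genes (camera adjusted p = 0.085). Wild type arrays 2 and 3 and mutant array 2 did not correlate best with their own number.

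Of the 15 shifted lists, 1 was called with an estimated correlation, and 0 with Y-linked signal as a covariate and an estimated correlation. Ribosome biogenesis kept its call in 20 of 21 settings, all but the latter. Cholesterol synthesis, stem cell, lysosome, macrophage, mast cell and immediate early genes kept theirs in 19 of 21, all but these 2. G2/M genes lost theirs in 11, megakaryocyte genes in 10, the mTOR, nucleotide synthesis and synthetase lists in 9 each, glycolysis in 6, heat shock in 5 and granulocyte genes in 4. Of lists not shifted, interferon-stimulated genes were called in 7 settings and FoxO targets in 6. The Rptor fold change kept its side of the threshold in every setting run. Of results called in the main fit or in the setting, 0 reversed. Lists called in neither were not counted. Among these, the insulin, ATF4, B cell and NRF2 lists changed direction with Y-linked signal as a covariate. The median log2 fold change of all genes was -0.07, and ran from -0.115 without wild type array 1 to 0.060 without the lower 50% of genes. Small changes are limited by 3 arrays per group, since 29.3% of simulated 2-fold changes were called.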

Other observations

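Some further values were not called. Fnip2, a partner of folliculin chosen after its values were seen, had a log2 fold change of 1.25 ± 0.19 (SE) with a limma adjusted p of 0.099. Among interferon-stimulated genes, Oas3 and Ifi27l2a had log2 fold changes of -1.05 ± 0.27 and -1.30 ± 0.36 and did not pass within the list (adjusted p of 0.058 and 0.076). Among 10092 probe sets that name no single gene, limma called 0, with 715 at an unadjusted p under 0.05. The ratio of 3' to 5' Gapdh control signal was 1.71 ± 0.25 (log2, SD, n = 3) in wild type and 1.39 ± 0.11 in mutant arrays (exact permutation p = 0.1, two-sided, the smallest this design allows). All wild type values (1.53 to 1.99) lay above all mutant values (1.33 to 1.52). What this difference does to gene values was not tested. The same ratio for Actin was -0.0018 and -0.0115 (exact p = 1), and the bioB hybridization control was 11.37 and 10.98 (exact p = 0.3).

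All tests below were chosen after the result was seen, except the direction of the 15 lists against wild type array 1 and the means of Flcn, Fnip1 and Rragc. The reading first planned for the former was changed after its outcome, as described with it.

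Whether other groupings of the arrays give as many calls cannot be settled with 10 splits of 6 arrays, whose share never falls under 0.05. The real split called 20 genes and the highest other split 0, and 1 of the 10 splits reached the real count. For the gene lists the real split called 15 and the highest other split 9, and again 1 of 10 reached the real count.

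The first pattern is the part overlap of genotype with Y-linked signal, which may reflect animal sex. Lists were judged by their median less the median of all genes. The 15 shifted lists all kept their direction when the mutants were set against wild type array 1 alone. By a bound set before that result was seen, 12 or more was to count against sex. That reading was dropped once the result was known, because the lists were called on means that include array 1 and because 1 array stands for its group. With Y-linked signal as a covariate, a fit that rests on the same array, 9 of the 15 lists were still called in the same direction, and with an estimated correlation in that fit 0 lists were called (smallest adjusted p 0.097). Of 27 genes not linked to sex that were called without wild type array 1, the median share of the difference that remained against it was 0.433, with 11 genes above 0.5. The 8 of them that are among the 20 changed genes kept shares of 0.755 to 1.04. Their call in the full fit, which includes array 1, favours high shares. Outside these 8, only Foxa3, Met and Slc6a15 kept a share above 0.5, and the lowest share was -0.226 (Nsmf). Against wild type array 1 all 20 kept 0.822 to 1.17 of their full difference, though they were called on means that include it. Sex and genotype cannot be told apart for these lists and genes, because a single wild type array lacks Y-linked signal.

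The second pattern is that mast cell, basophil and macrophage genes were higher and neutrophil granule genes lower in mutant sorts. A lower share of the main cell type would raise other cell types alike. The lower of the mast cell and macrophage medians lay 0.339 above the highest of the B cell, T cell, erythroid and megakaryocyte medians, with a standard error of 0.170 over list members and 0.108 over arrays. That gap is under 2 standard errors over members, so for the rise alone this explanation stays open. A bound first set without the spread counted against it and was changed after its outcome. For the whole pattern, the lower of the 2 risen medians lay 0.966 above the granulocyte median, with a standard error of 0.344 over members and 0.175 over arrays. A uniform rise does not describe lower granulocyte genes. That gap cannot decide the question, because the pattern was chosen for it after the values were seen. The granulocyte shift was also not called with an estimated correlation (camera adjusted p = 0.144). Mature mast cells stay open, since Mcpt4, Tpsab1 and Tpsb2 had a median log2 change of -0.061 while the chymase gene Cma1 rose by 2.15. A bound first set without Cma1 counted against them and was changed after its outcome. Late neutrophil RNA in the wild type sorts, which the lineage gate should remove, remains a candidate source: 9 of 9 late genes were lower (S100a9 stood at a log2 signal of 13.5 in wild type, S100a8 at 12.3) while 5 early granule genes had a median of 0.19 (from -0.59 to 0.39, with 1 lower), though several of the late genes had been seen to fall. Basophils or their progenitors in the mutant sorts stay open, with 5 of 6 marker genes changed by over 0.2 (log2) and 3 at an unadjusted p under 0.05 in limma. An altered progenitor state and the Cre transgene itself, which were not tested, stay open as well. Animal sex stays open too: the mast cell, macrophage and granulocyte lists kept their direction against wild type array 1, but that is 1 array. Their medians against it were 0.46, 0.43 and -0.58. These have the median of all genes subtracted, unlike the medians of the covariate fit.

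The third pattern is the lower level of stem cell genes. Without Egr1 and Nr4a1, which are also immediate early genes, the median was -0.548 (camera adjusted p = 3.1e-05, and adjusted p = 0.144 with an estimated correlation). These 2 genes alone therefore do not make the shift. Leaving out 2 of 33 members can hardly move a median, and other members were not examined for such a response. The test thus cannot exclude an immediate early response in wild type sorts. Uniform dilution by cells that lack all these genes, as the only cause, is argued against by the spread of 18 members, from -2.30 to 0.76. These are the members with a wild type mean of at least 9 (log2). Equal response of all probe sets to dilution was assumed. A simulated heterogeneity test gave 1e-04, the smallest value that 10000 draws can give. The draws took genes as independent, while the estimated correlation of the whole list was 0.10, so that value is not exact. Equal changes were the only form of dilution examined, and dilution by cells that express some of these genes stays open. An immediate early response, a changed mix of stem and progenitor cells within the gate, a change in each cell and animal sex may each contribute and stay open.

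A hypothesis concerns transcription factors of the MiT/TFE family, which drive lysosomal genes. Rragd, Fnip2 and Gpnmb, picked for their change, had log2 fold changes of 0.98, 1.25 and 3.32, with limma adjusted p of 0.22, 0.099 and 0.16 over all genes. The other 3 targets, not picked for their change, Flcn, Fnip1 and Rragc, had log2 fold changes of 0.76, 1.07 and 0.39, with a mean of 0.743. These 6 changes go in the direction of raised MiT/TFE activity. The limma adjusted p of Flcn, Fnip1 and Rragc were 0.24, 0.29 and 0.56, so none of the 6 passed over all genes. A larger share of macrophage-like or mast-like RNA could give the same. The autophagy list did not shift, with a median of -0.03 over 33 genes (camera adjusted p = 0.940).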
